A study of Homo sapiens with 6 samples.

How the data were processed

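The data were 6 gene expression arrays of human T cells from blood mononuclear cells of healthy donors. Per the labels, the cells were sorted with tetramers of CD1d, the lipid-presenting molecule, loaded with 1 of 3 glycolipids. The 3 lipids were LGL1 (lysoglucocerebroside, a glucose linked to sphingosine with no fatty acyl chain), bGL1-22 (a beta-glucosylceramide with the same head group and a long fatty acyl chain) and aGalCer (alpha-galactosylceramide, the classical ligand of invariant NKT cells). Each of the 3 sorted populations had 1 unstimulated and 1 stimulated array. The labels' protocols describe stimulation by beads carrying CD3 and CD28 antibodies and, for part of the work, culture with CD1d-expressing cells given lipid or none, and they do not say which of these the arrays followed. The labels name neither separate cultures nor separate donors. The p-values below therefore measure only the spread between these samples, which may be technical in part.

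RNA was hybridised to Affymetrix Human Genome U133 Plus 2.0 arrays and analysed by the authors with GeneSpring GX 12.5, per the series' design text. How probe sets were summarised and how arrays were normalised is not given in the sources used here. The deposited values are on a log scale, taken here as log2 because the base is not stated. In the deposited log2 values each of the 54675 probe sets was centred on its median over the 6 arrays (all 54675 medians lay within 1e-06 of 0), and values ran from -7.3 to 7.61. A centred value gives differences between arrays and no level, so a gene near background cannot be told from a well expressed one, and no detection call or background measure was used here. Array medians lay between -0.0081 and 0.0037.

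Of the 54675 probe sets, 62 were controls, 41091 had 1 gene symbol in the platform annotation, 1801 had several and 11721 had none. Probe sets with several symbols or none were not used. A further 201 were left out because their genes are sex chromosome markers or follow a common inherited presence or absence. The remaining 40890 probe sets were averaged per gene into 19667 genes, of which 9194 had 1 probe set and 10473 had several. The annotation's symbols were set against RefSeq genes of assembly GRCh38.p14 through the gene ID, and 0 needed an update. No coordinates are given because the annotation names no build. No columns were left unmapped, and file columns were tied to samples through the labels.

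Groups, tests, gene lists, alternatives and the rule for named genes were fixed before the data were examined. The centring forced changes from that plan. The plan took the probe set with the highest mean as the value of a gene, which has no meaning on centred values. The mean of the probe sets, planned as an alternative, became the main value, and the highest-mean rule was run as the alternative. The planned filters on dim probe sets could not be applied. Quantile normalization was not run because it would distort centred deviations, and a variance trend over mean level could not be fitted. Random lists for population comparisons were matched on the SD over the 6 arrays in place of the mean level, in 10 bins.

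Stimulation was tested with limma 3.58.1 in R 4.3.3 (Python 3.11.15 prepared the tables), with population and stimulation as terms, moderated variances, two-sided tests and Benjamini-Hochberg adjustment at 0.05 over all genes. The 3 populations were the 3 units, leaving 2 residual degrees of freedom and 3.74 prior degrees of freedom. A mean ± SD given with n = 3 is the mean and SD of the 3 populations' stimulated-minus-unstimulated differences. Populations were contrasted in the same additive limma model. Its p-values are too small as measures of population differences, since the 2 arrays of a population are not stated to be separate cultures. Genes that set 1 population apart were counted without a test, as genes at least 1 log2 (2-fold) higher or lower than both other populations in both states. That count was set beside 100 simulations with no population effect. A test of whether the response of the aGalCer population differed from that of the others was added after the data were examined. It compares 1 difference with 2 in limma, with 1 residual degree of freedom.

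Of 26 gene lists written in advance, 25 were tested, covering 414 of 466 genes. The receptor segment list had 0 of its 8 genes measured. Lists were tested with camera at its preset inter-gene correlation of 0.01, with an estimated correlation and with fry as alternatives. Differences of lists between populations are medians with their percentile among 10000 random lists, a description of these arrays. The text names the 10 largest rises and 10 largest falls among genes past the threshold with the same sign in all 3 populations, and the 2 highest and 2 lowest members of each list. It further draws on a fixed panel of immune genes, the 10 genes in each direction that most set the aGalCer population apart, 5 in each direction for the others, and the 5 largest changes of each population. Among the last, SHC4 (a response of 4.86 in aGalCer-specific cells) and FBLN5 (-3.43 in LGL1-specific cells) are named only here. Genes named for a different response in the aGalCer population, and members of lists outside this rule, were chosen after their values were seen. Some panel genes, among them PDCD1, CD40LG and CSF2, were not analysed here.

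The scripts were tested on simulated data with 19667 genes and 10 runs. With variances drawn from the fitted prior, the stimulation test recovered 92.8% of 200 genes changed by 1 log2 and 99.6% of those changed by 2 log2, and 5.05% of its calls were unchanged genes. The population contrast recovered 99.3% of genes changed by 2 log2, with 4.56% false calls, and the difference of responses recovered 99.2% of genes changed by 3 log2, with 8.74% false calls. With each gene's own estimated variance, the false shares were 8.41%, 10.4% and 19.3%. Camera called the shifted list in 10 of 10 runs and called other lists 0 times in the former simulation and 8 times in the latter. The simulated genes varied independently of one another, so these runs cannot show how correlation between genes affects the list calls.

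Alternatives were centring each array on its median, the highest-mean or largest-SD probe set per gene, robust variances, no population block, each population left out, both beta-glucosyl lipid populations averaged as 1 unit, other thresholds, and each state alone. The closing section gives their effect. The number of arrays, 1 per population and state, limits the precision of every value.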

Results

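Gene expression was measured on 6 arrays of CD1d tetramer-sorted human T cells. LGL1-specific, bGL1-22-specific and aGalCer-specific cells (the last being invariant NKT cells) each had 1 unstimulated and 1 stimulated array. The design compares stimulated with unstimulated cells, cells specific for the beta-glucosyl lipids with invariant NKT cells, and the populations specific for the related lipids LGL1 and bGL1-22. All values are log2 differences between arrays, since the deposited values are centred per probe set and hold no levels. Control RNAs differed both with stimulation and with population. The 24 probe sets for poly-A spike-ins averaged 0.89, 0.14 and -0.03 on the unstimulated aGalCer, LGL1 and bGL1-22 arrays. On the stimulated arrays they were lower in all 3 populations, at 0.08, -0.45 and -0.40. The 18 probe sets for hybridization controls were also lower after stimulation, at -0.04, -0.03 and -0.07 against 0.35, 0.10 and -0.01.

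Most of the 10 largest rises with stimulation were those of cytokine genes. IL3, a growth factor for myeloid cells, rose by 6.38 ± 1.62 (mean ± SD of 3 populations, n = 3; limma adjusted p = 0.000569) and IFNG, the main type 1 cytokine, by 5.07 ± 0.31 (adjusted p = 4.05e-05), each in 3 of 3 populations. The anti-inflammatory IL10 rose by 4.67 ± 0.93, the eosinophil growth factor IL5 by 4.53 ± 0.26, and IL13, a type 2 cytokine, by 4.09 ± 0.91. LTA, a relative of TNF, rose by 4.22 ± 0.54, and the neutrophil chemokine CXCL8 by 3.75 ± 0.18. The cytokine LIF (3.72 ± 0.52), the transcription factor ZBED2 (4.26 ± 0.79) and the coagulation factor F5 (3.70 ± 0.28) completed the 10 largest rises.

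The 10 largest falls lay between -4.02 and -3.01. RAB37, a vesicle GTPase, fell by 4.02 ± 0.37 (SD, n = 3; limma adjusted p = 6.61e-05), PLAAT4, a phospholipid-metabolising enzyme, by 3.88 ± 0.15, and the receptor tyrosine kinase KIT by 3.79 ± 0.54, in 3 of 3 populations. IL7R, the IL-7 receptor chain, changed by -3.38 with an SD of 0.03. The granzyme GZMK changed by -3.26 ± 0.37, the B cell survival factor TNFSF13B by -3.66 ± 0.50, and the lymphocyte GTPases GIMAP4 and GIMAP1 by -3.13 ± 0.53 and -3.07 ± 0.31. RIPOR2 changed by -3.41 ± 0.50 and the extracellular adenosine deaminase ADA2 by -3.01 ± 0.48.

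**Figure D1:**
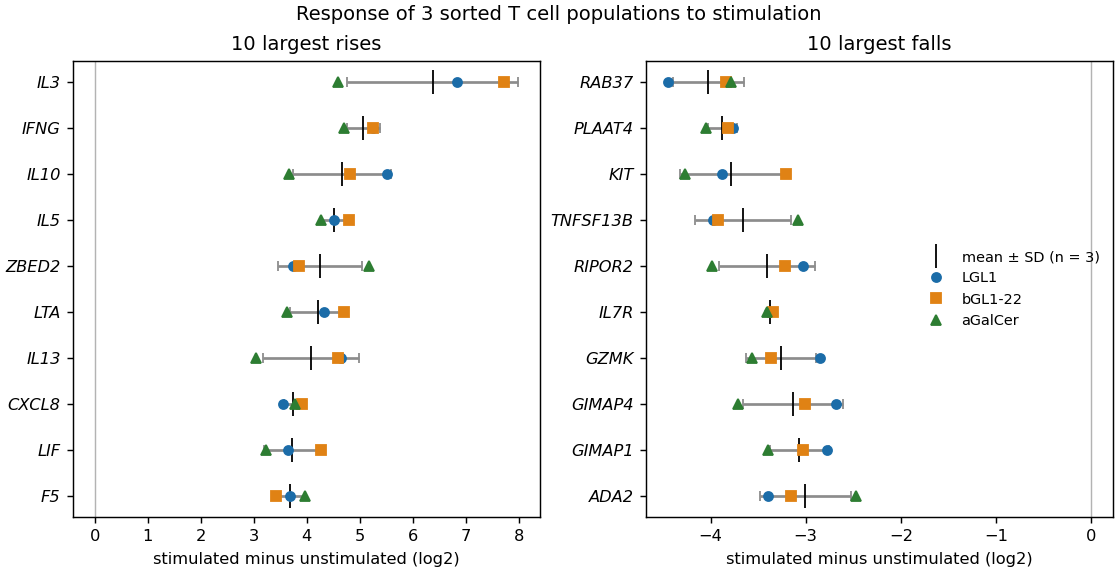
Stimulated minus unstimulated difference (x axis, log2) of the 10 genes with the largest mean rise and the 10 with the largest mean fall; each symbol is 1 population, the vertical tick is the mean and the bar the SD of the 3 populations. IL3 spanned 4.58 in the aGalCer to 7.72 in the bGL1-22 population, while IL7R lay between -3.40 and -3.34 in all 3.

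In all, 3379 genes rose, 3220 fell and 13068 did not pass (limma, adjusted p under 0.05, 3 populations as the units). Of these, 644 rose and 570 fell by at least 1 log2. Without the bGL1-22 population 2100 genes fell. The poly-A controls moved with the same contrast, from 0.14 to -0.45 in LGL1, from -0.03 to -0.40 in bGL1-22 and from 0.89 to 0.08 in aGalCer-specific cells. Responses of at least 1 log2 in the same direction in all 3 populations numbered 440 up and 369 down, against 0.849 and 0.628 for independent lists. Those expected counts give every gene the same chance to change, so the excess over them is no measure of agreement. The responses correlated across 19667 genes, which are not independent replicates, with r = 0.931 between LGL1 and bGL1-22, 0.836 between LGL1 and aGalCer and 0.827 between bGL1-22 and aGalCer.

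Among the fixed panel, the activation marker IL2RA (the IL-2 receptor alpha chain) rose by 2.63 ± 0.18 (SD, n = 3; limma adjusted p = 6.36e-05). The costimulator ICOS rose by 2.35 ± 0.30, TNF by 2.87 ± 0.33, IL2 by 3.20 ± 1.22, IL4 by 3.41 ± 0.78, IL17A by 2.16 ± 1.05, the granzyme GZMB by 1.67 ± 0.45, the type 1 regulator TBX21 by 0.96 ± 0.14 and IL21, a follicular helper cytokine, by 0.92 ± 0.20. IL2 and IL17A have 2 probe sets each. The highest-mean and the largest-SD rule both picked the one that rose, by 6.26 for IL2 and 4.26 for IL17A. On centred values both rules choose by the deviations themselves, so their agreement is no independent check. The averages above are lower because the other probe set changed far less. BCL6, the follicular helper regulator, changed by -1.61 ± 0.46 (adjusted p = 0.00103), but by -0.34 with the highest-mean probe set, which did not pass (adjusted p = 0.0509), and by -3.20 with the largest-SD probe set (adjusted p from 0.000451 to 0.0509 over the alternatives). The type 2 regulator GATA3 changed by -0.79 ± 0.41 (adjusted p = 0.01), a call lost without the population block (0.0657; from 0.00188 over the alternatives).

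CD8A, a coreceptor chain, changed by -0.66 ± 0.49 (limma adjusted p = 0.0352), a call lost without the LGL1 population (-0.54, adjusted p = 0.149), without the bGL1-22 population (-0.51, 0.177) and without the population block (adjusted p = 0.631, the highest over the alternatives, the lowest being 0.000148). CD69, an early activation marker, had a mean of 0.64 ± 0.71 (adjusted p = 0.107) and passed only without the aGalCer population (1.04, adjusted p = 0.000273; up to 0.407 over the other alternatives). CXCR5 (0.25, adjusted p = 0.0734), PRF1 (0.06, 0.607), ZBTB16 (-0.02, 0.904), FOXP3 (0.16, 0.138) and CD4 (-0.11, 0.35) did not pass. Under 1 alternative each, CXCR5 passed without the aGalCer population (0.30, adjusted p = 0.045; up to 0.384 over the alternatives) and FOXP3 with the largest-SD probe set (0.37, 0.023; up to 0.811 with the highest-mean probe set, where its value was -0.04).

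Genes that make ribosomes rose as a whole list. All 17 measured ribosome biogenesis genes rose over all genes and 17 when adjusted over the list alone, led by BYSL (2.90 ± 0.36) and NOLC1 (2.32 ± 0.22), which act in ribosome assembly (camera adjusted p = 6.8e-12; adjusted p = 0.309 with an estimated correlation). Amino acid genes rose in 13 of 18 and fell in 2 (14 and 2 adjusted over the list alone; adjusted p = 0.000213, and 0.309 with an estimated correlation). SLC7A5 and SLC3A2, the paired chains of a leucine transporter, rose by 2.42 ± 0.23 and 1.58 ± 0.24, while the transporters SLC1A4 and SLC38A2 changed by -1.60 and -0.42. Unfolded protein response genes rose in 13 of 18 and fell in 1 (14 and 1 adjusted over the list alone; adjusted p = 0.00013, and 0.309 with an estimated correlation), with SDF2L1 at 1.14 ± 0.16 and MANF at 1.09 ± 0.06 highest, HERPUD1 at -0.10 (not past) and DDIT3 at -0.49 ± 0.08 lowest.

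Cholesterol and fatty acid synthesis genes rose in 10 of 16 and fell in 0 (10 and 1 adjusted over the list alone; camera adjusted p = 0.00879, and 0.386 with an estimated correlation), with HMGCS1, an early enzyme of the sterol pathway, at 1.57 ± 0.59 and the sterol carrier STARD4 at 1.22 ± 0.68. LSS (-0.16) and INSIG1 (-0.23) did not pass. Glycolysis genes rose in 8 of 17 and fell in 2 (9 and 2 adjusted over the list alone; adjusted p = 0.0226, and 0.516 with an estimated correlation). The glycolysis call also ended with the highest-mean probe set (adjusted p = 0.0636), without the aGalCer population (0.112) and under fry (0.0672). The hexokinase HK2 rose by 1.49 ± 0.35 and PGAM1 by 0.77 ± 0.16, and the aldolase ALDOC and the phosphofructokinase PFKL changed by -1.09 ± 0.77 and -0.38 ± 0.03. Heat shock and stress genes rose in 8 of 15 and fell in 2 (9 and 2 adjusted over the list alone; adjusted p = 0.0131, and 0.309 with an estimated correlation), with the chaperones HSPH1 at 1.83 ± 0.10 and HSPE1 at 1.73 ± 0.41, against HMOX1 at -0.93 ± 0.16 and DDIT4 at -0.41 ± 0.12.

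Early T cell receptor response genes rose in 11 of 24 and fell in 0 (13 and 0 adjusted over the list alone; camera adjusted p = 3.5e-06, and 0.309 with an estimated correlation), with IER3 at 3.05 ± 1.04 and the growth regulator MYC at 2.70 ± 0.39. TNFAIP3 (0.03) and TNFRSF18 (0.02) did not pass. Type 1 genes rose in 9 of 13 and fell in 4 (9 and 4 adjusted over the list alone; adjusted p = 0.0112, and 0.386 with an estimated correlation), the falls including the chemokine CCL5 (-1.88 ± 0.47) and the signal transducer STAT4 (-0.79 ± 0.34). Type 2 genes rose in 9 of 15 and fell in 2 (10 and 3 adjusted over the list alone; adjusted p = 0.00879, and 0.386 with an estimated correlation), with CCR8 lowest but for GATA3, at -0.73 ± 0.25. Type 17 genes rose in 7 of 10 and fell in 1 (8 and 1 adjusted over the list alone; adjusted p = 0.0103, and 0.386 with an estimated correlation), with the cytokine IL17F at 3.66 ± 1.76 and the chemokine CCL20 at 3.29 ± 0.65 highest, AHR (0.14) not past and RORA at -0.29 ± 0.16 lowest. The type 17 call ended without the population block (adjusted p = 0.0681) and under fry (0.056), and the median change was 0.13 in aGalCer-specific cells against 1.13 and 1.10 in LGL1 and bGL1-22 cells.

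Interferon-stimulated genes fell in 14 of 23 and rose in 0 (18 and 0 adjusted over the list alone; camera adjusted p = 1.26e-07, and 0.309 with an estimated correlation), with EPSTI1 at -2.0 ± 0.42 and XAF1 at -1.74 ± 0.40 lowest, and GBP2 (0.08) and USP18 (-0.03) not past. Pan T cell genes fell in 10 of 14 and rose in 0 (10 and 0 adjusted over the list alone; adjusted p = 3.58e-05, and 0.309 with an estimated correlation), including the receptor modulator CD5 (-1.09 ± 0.24) and the kinase LCK (-1.06 ± 0.23). CD4 and CD6 (-0.12) did not pass. Chemokine receptor and homing integrin genes fell in 12 of 21 and rose in 2 (13 and 5 adjusted over the list alone; adjusted p = 0.0075, and 0.309 with an estimated correlation), with ITGA1 at -2.06 ± 0.08, CCR2 at -1.82 ± 0.70, CCR6 at 1.08 ± 0.89 and GPR183 at 0.77 ± 0.17. NK receptor and innate-like genes fell in 9 of 18 and rose in 1 (9 and 1 adjusted over the list alone; adjusted p = 0.00589, and 0.309 with an estimated correlation), with the NK receptor KLRB1 at -2.66 ± 0.95, CXCR6 at -1.63 ± 0.43 and SLAMF1 at 0.95 ± 0.03. CD160 averaged 0.69 and did not pass. Naive and central memory genes fell in 7 of 14 and rose in 2 (7 and 3 adjusted over the list alone; adjusted p = 0.0226, and 0.309 with an estimated correlation), with IL7R, CD27 (-2.40 ± 0.11) and, in the other direction, the repressor BACH2 (1.12 ± 0.34). CCR7 averaged 0.41 and did not pass. Without the population block the calls of the NK receptor list (adjusted p = 0.0681) and of the naive and central memory list (0.116) ended.

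The next 4 lists were not called by camera, which compares a list with other genes, and were called by fry, which tests a list against no change. Of 18 follicular helper genes, 7 rose and 5 fell (9 and 6 adjusted over the list alone; camera adjusted p = 0.409, fry 0.0209). The B cell attracting chemokine CXCL13 rose by 3.49 ± 2.71 (adjusted p = 0.0332), a call that without the LGL1 population was lost (2.68, adjusted p = 0.128), as it was without the bGL1-22 population (2.73, 0.166). Over all alternatives its adjusted p ran from 2.85e-06, without the aGalCer population, to 0.168. SLAMF6, a receptor of lymphocyte contacts, changed by -2.15 ± 0.06. Cytotoxic genes rose in 3 and fell in 9 of 17 (3 and 9 adjusted over the list alone; adjusted p = 0.113, fry 0.0119), with GZMH at 2.07 ± 1.07, the death ligand FASLG at 1.97 ± 0.42 and CTSW at -1.30 ± 0.02. Regulatory T cell genes rose in 4 and fell in 1 of 12 (4 and 2 adjusted over the list alone; adjusted p = 0.406, fry 0.0209), with the inhibitory receptor CTLA4 at 1.97 ± 0.21, the ectoenzyme ENTPD1 at -1.72 ± 0.23 and RTKN2 at -0.50 (not past). Inhibitory receptor genes rose in 5 and fell in 5 of 11 (5 and 6 adjusted over the list alone; adjusted p = 0.415, fry 0.0116), with the ligand CD274 at 1.43 ± 0.76, CD96 at -2.43 ± 0.06 and LAIR1 at -1.23 ± 0.30.

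**Figure D2:**
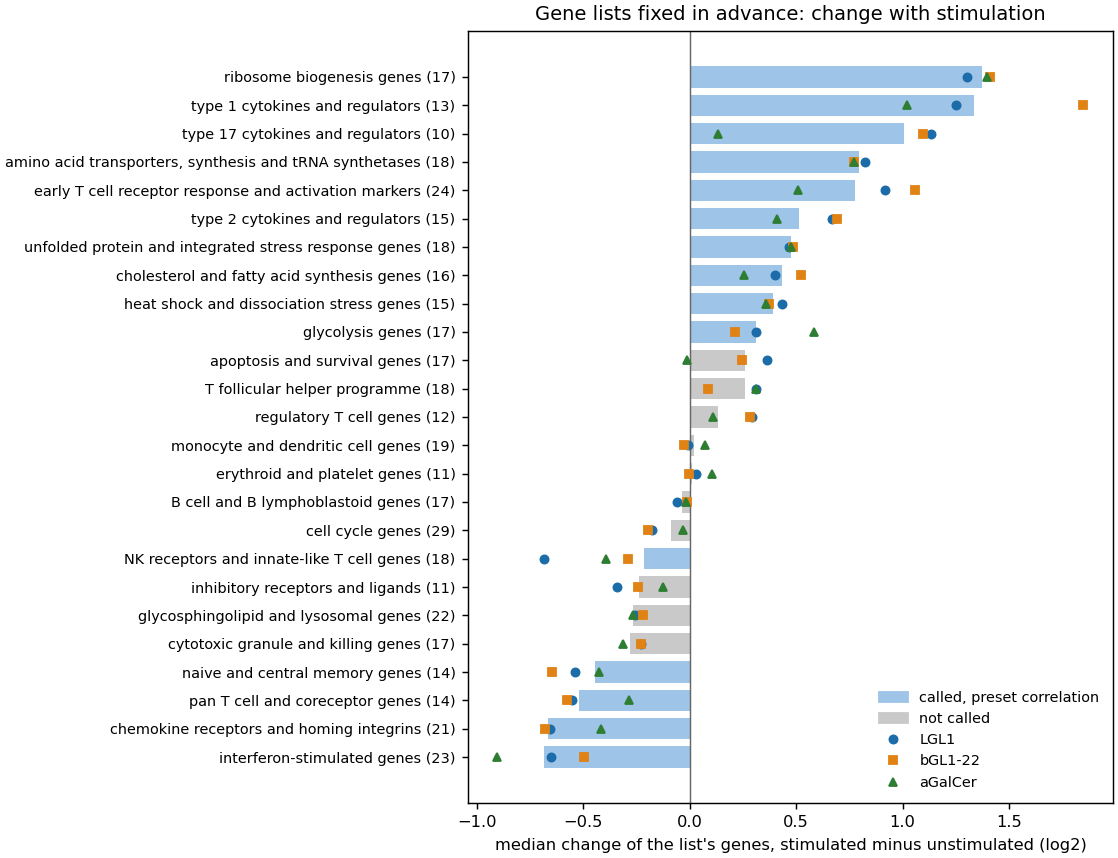
Median stimulated minus unstimulated change of the genes of each list (x axis, log2), with the number of measured genes in brackets; bars are medians of the mean change, symbols the medians in each population, and blue bars mark lists called by camera at the preset correlation. Ribosome biogenesis genes were highest (median 1.37) and interferon-stimulated genes lowest (median -0.69).

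Few markers of other cell types passed the test of stimulation. B cell genes rose in 0 and fell in 3 of 17 (0 and 3 adjusted over the list alone; camera adjusted p = 0.406), with FCER2 (0.15) and EBF1 (0.15) not past and BLK and MS4A1 at -0.61 ± 0.33 and -0.51 ± 0.32. Monocyte and dendritic cell genes rose in 1 and fell in 4 of 19 (1 and 4 adjusted over the list alone; adjusted p = 0.785), with S100A12 at 0.30 ± 0.14, CD14 at 0.22 (not past), LYZ at -1.45 ± 1.13 and CTSS at -1.24 ± 0.35, and their median (0.02) and mean (-0.13) differed in sign. Erythroid and platelet genes rose in 0 and fell in 0 of 11 (0 and 0 adjusted over the list alone; adjusted p = 0.859); GP9 (0.23), HBD (0.13), SLC4A1 (-0.09) and TUBB1 (-0.12) lay at the ends.

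Of 25 lists, 15 were called at the preset correlation, 10 higher and 5 lower. With an estimated correlation 0 were called, 2 had an unadjusted p under 0.05 and the smallest adjusted p was 0.309, while fry, which does not compare a list with other genes, called 18. The lower poly-A controls of the stimulated arrays went with all of these list changes. Averaging the LGL1 and bGL1-22 populations as 1 unit left 4687 genes past the threshold, 4681 of them shared with the 6599 of the 3-unit test, and leaving out the LGL1 or bGL1-22 population left 4582 or 4371.

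The aGalCer-specific cells stood apart from both other populations in both states. CA2, a carbonic anhydrase, was 3.65 to 4.26 log2 higher in aGalCer-specific cells over the 4 comparisons (2 populations, 2 states, 1 array each), and IL23R, a receptor chain of type 17 cells, 3.19 to 4.12 higher. The IL-25 receptor chain IL17RB was lower, with differences of -3.12 to -2.97, and the lymph node homing receptor CCR7 differed by -3.63 to -2.35. In limma's additive model CA2 (LGL1 minus aGalCer adjusted p = 0.00124; bGL1-22 minus aGalCer 0.00108) and IL17RB (0.000697; 0.000745) were past the threshold. ZBTB16, the transcription factor of invariant NKT cells, was 1.47 to 2.35 higher in aGalCer-specific cells (adjusted p = 0.00549; 0.00227), and CD8A differed by -2.70 to -1.56 (0.0096; 0.0125).

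Further genes higher in aGalCer-specific cells, given by the smallest of the 4 differences, were SCRN1 (2.73), the fatty acid elongase ELOVL4 (2.47), the malic enzyme ME1 (2.46), the caveolar protein CAV1 (2.38), the metalloprotease ADAM12 (2.27), the amino acid oxidase IL4I1 (1.99), LST1 (1.94) and the chemokine CCL20 (1.89). Further genes lower in them were the T cell receptor delta segment TRDV3 (-2.70), the mannosidase MAN1C1 (-2.68), the protease inhibitor SPINT2 (-2.47), the kinase inhibitor PKIA (-2.32), the inhibitory receptor TIGIT (-2.28), the oxysterol receptor GPR183 (-2.17), KISS1R (-2.16) and CLC (-2.15). With the highest-mean probe set TRDV3 differed by -0.59, ME1 by 3.92 and ADAM12 by 3.91, and with the largest-SD probe set by -4.64, 3.69 and 3.91.

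**Figure D3:**
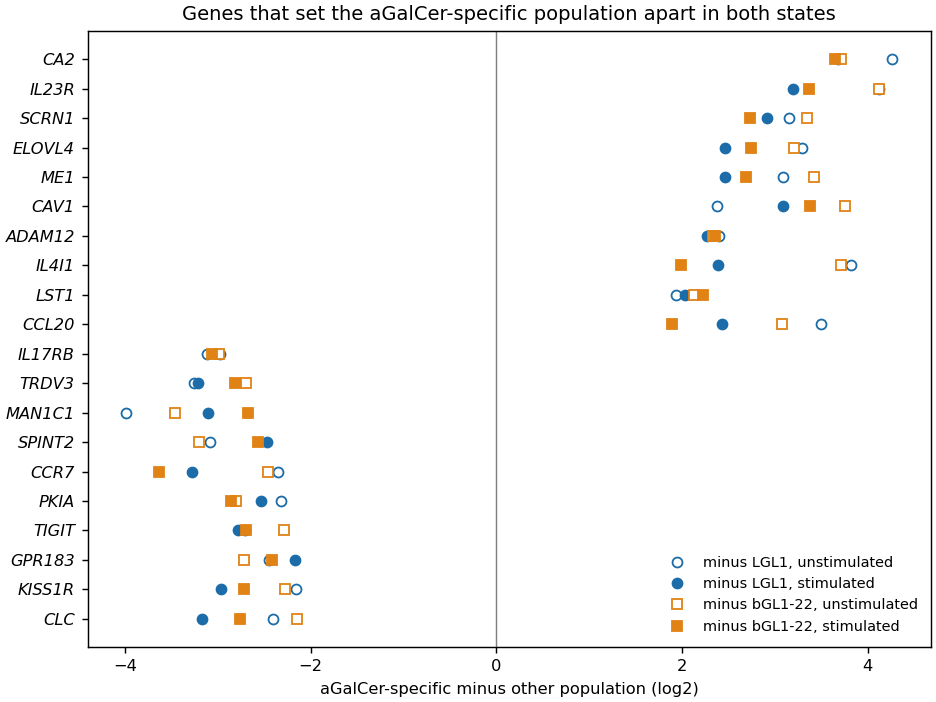
Difference of the aGalCer-specific population from the LGL1 (circles) and bGL1-22 (squares) populations (x axis, log2) in unstimulated (open) and stimulated (filled) cells, 1 array each, for the 10 genes most higher and the 10 most lower. CA2 lay at 3.65 or more and IL17RB at -2.97 or less in all 4 comparisons.

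In total 122 genes were at least 1 log2 apart in all 4 comparisons, 39 higher and 83 lower in aGalCer-specific cells, against 2 for LGL1-specific and 4 for bGL1-22-specific cells. Simulations without a population effect gave at most 2. They drew independent noise for each array, with no culture, donor or input effect shared by the arrays of a population. On the stimulated arrays alone the counts were 223, 3 and 7, and on the unstimulated arrays alone 315, 7 and 14. The largest-SD probe set gave 233 for aGalCer. Between LGL1 and aGalCer, 324 genes were higher in LGL1-specific and 216 in aGalCer-specific cells (limma, adjusted p under 0.05), and between bGL1-22 and aGalCer, 417 and 297. These p-values are too small, as the arrays of a population are not stated to be separate cultures. GAPDH probe sets from the 3' end exceeded those from the 5' end by 0.21 and 0.22 on the aGalCer arrays, relative to the typical array, against -0.10 to 0.03 on the other 4. The same ratio of ACTB did not separate them, at 0.03 and 0.15 on the aGalCer arrays and between -0.36 and 0.10 on the others.

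Gene lists also lay apart between these populations. Interferon-stimulated genes were lower in aGalCer-specific cells: the median of 23 genes was 0.49 and 0.52 higher in unstimulated LGL1 and bGL1-22 cells and 0.66 and 0.84 higher in stimulated ones, all at percentile 100 of 10000 random lists. Naive and central memory genes were 1.23 and 0.99 higher in the unstimulated beta-glucosyl lipid populations and 0.37 and 0.38 higher after stimulation (percentiles 100, 100, 99.7 and 99.7). Cell cycle genes were 0.46 and 0.51 higher in unstimulated and 0.34 and 0.46 higher in stimulated LGL1 and bGL1-22 cells. Type 2 genes differed most after stimulation, by 0.91 and 1.13 (percentile 100 in both), and 0 of 15 members was at least 1 log2 higher in stimulated aGalCer-specific cells. Follicular helper genes were 0.28 and 0.55 higher in unstimulated and 0.30 and 0.40 higher in stimulated LGL1 and bGL1-22 cells (percentiles 97.8, 100, 99.2 and 99.8). Other lists were higher in unstimulated aGalCer-specific cells. LGL1 and bGL1-22 cells differed from them by -0.55 and -0.59 in type 1 genes (percentile 0.1 in both), by -0.30 and -0.33 in early T cell receptor response genes (0.1 in both), by -0.28 and -0.30 in apoptosis and survival genes (0.2 in both) and by -0.20 and -0.40 in NK receptor and innate-like genes (2.5 and 0.1). After stimulation these differences were -0.33 and -0.15 (0.1 and 7.2), 0.06 and 0.15 (63.9 and 93.6), 0.03 and 0.08 (51.3 and 74.4), and -0.01 and -0.28 (27.8 and 0.1). In unstimulated cells the NK receptor and innate-like list was split. Of its 18 members, 3 were at least 1 log2 higher and 4 lower in LGL1-specific than in aGalCer-specific cells. For bGL1-22-specific cells these counts were 2 and 8. Heat shock and stress genes were 0.27 and 0.29 higher in unstimulated and 0.25 and 0.22 higher in stimulated LGL1 and bGL1-22 cells (percentiles 98.7, 99.1, 99.2 and 98.3). B cell genes were 0.08 and 0.17 higher in unstimulated and 0.08 and 0.09 higher in stimulated ones (percentiles 89.2, 99.2, 92.6 and 93.4). Each value compares 1 array with 1 array and has no replicate check. The poly-A controls and the GAPDH ratio, but not the ACTB ratio, differed with the same populations.

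Responses to stimulation differed between aGalCer-specific and the other cells in a small part of the genes. CXCL13 rose by 5.10 in LGL1 and 5.01 in bGL1-22 cells and by 0.36 in aGalCer-specific cells, a difference of -4.70 (limma adjusted p = 0.000285). The lower response of CXCL13 went with a high unstimulated value: unstimulated aGalCer-specific cells were 4.93 and 4.67 above the unstimulated LGL1 and bGL1-22 cells, while stimulated cells differed by 0.19 and 0.02. CD83, an activation marker, followed the same course (2.17, 2.34 and -0.14; difference -2.40, adjusted p = 0.00495), with unstimulated aGalCer-specific cells 2.71 and 2.80 higher. The poly-A controls were highest on that unstimulated array. IL22, a type 17 cytokine, instead stayed low after stimulation in aGalCer-specific cells (responses 3.71, 3.81 and 0.16; difference -3.60, adjusted p = 0.000814), with stimulated differences of -3.96 and -4.68 from LGL1 and bGL1-22 cells. PTGS2, the inducible prostaglandin synthase, did likewise (4.44, 4.60 and 1.09; difference -3.43, adjusted p = 0.000964), with stimulated differences of -3.95 and -3.96.

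The difference was also past the threshold for IL3 (-2.69, adjusted p = 0.03), IL2 (-2.07, 0.0164), IL17A (-1.80, 0.00991) and IL13 (-1.57, 0.00831), all of which rose less in aGalCer-specific cells, and for ZBED2 (1.37, 0.0136), which rose more. In total 97 genes had a higher and 134 a lower response in aGalCer-specific cells, out of 19667 tested. For ZBED2, aGalCer-specific cells differed from LGL1 and bGL1-22 cells by -2.06 and -1.89 unstimulated and by -0.63 and -0.57 stimulated. Its larger rise thus started from a lower unstimulated value. The slope of the aGalCer response on the mean of the others was 0.887 over the 6599 genes changed by stimulation. Those genes were called partly for agreement between the populations, so the slope is not a free measure of how alike the responses are. The test compares 1 difference with 2, so it holds no measure of the spread of the aGalCer response. Its count fell from 231 to 126 with each array centred on its median, and was 502 with the largest-SD probe set.

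**Figure D4:**
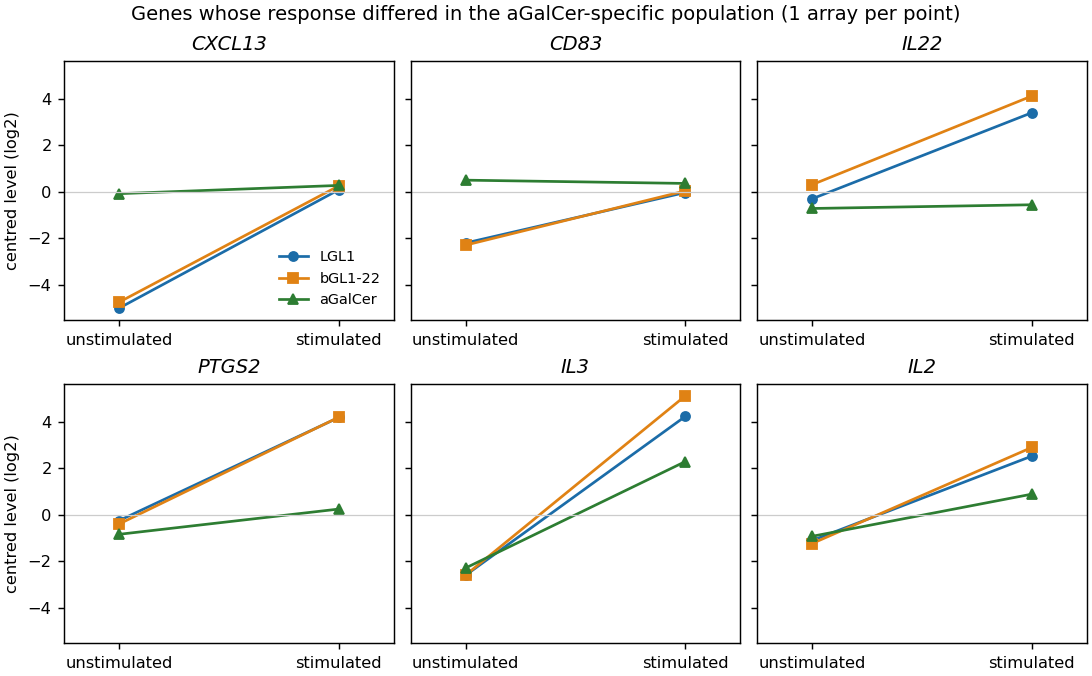
Centred log2 level (y axis, 0 is the gene's typical value over the arrays) of 6 genes in unstimulated and stimulated cells, 1 array per point, for LGL1 (circles), bGL1-22 (squares) and aGalCer (triangles) cells. CXCL13 and CD83 were already high in unstimulated aGalCer-specific cells, whereas IL22 and PTGS2 stayed low in stimulated ones.

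LGL1 and bGL1-22 share the beta-linked glucose and the sphingosine and differ by the fatty acyl chain, which LGL1 lacks. Between the cells specific for them, 6 genes were at least 1 log2 apart in both states, and 0 genes passed the test of the difference. EPHX4, an epoxide hydrolase, had an LGL1 minus bGL1-22 value of 1.08 (95% interval 0.85 to 1.31) and SPINK2, a protease inhibitor, of 1.09 (0.46 to 1.71). The values were -1.49 for CXCL8 (-1.75 to -1.22), -1.58 for the adaptor DOK5 (-2.25 to -0.90), -1.25 for the actin bundler PLS3 (-1.61 to -0.90) and -1.11 for the proteoglycan SPOCK1 (-1.34 to -0.89). Adjusted p-values were 0.158 for EPHX4, CXCL8 and SPOCK1, 0.345 for PLS3 and 1 for SPINK2 and DOK5. These are the 2 and 4 genes that lay at least 1 log2 above both other populations. Since they were picked for their distance, their unadjusted intervals give the size and are no test.

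Smaller values with the same sign in both states, also not past the test, were those of the NK receptor chain KLRD1 (0.76, interval 0.54 to 0.97), HOMER2 (0.81, 0.58 to 1.03) and KLRC4 (0.77, -0.55 to 2.09), higher in LGL1-specific cells. The receptor ligand CD200 (-0.94, -1.14 to -0.75) was higher in bGL1-22-specific cells. Genes lower in bGL1-22-specific cells than in both others included the adaptor TYROBP (0.95, 0.59 to 1.30), LIM2 (0.95, 0.69 to 1.20), SPRY2 (1.15, lower bound 0.79), the NK receptor KLRG1 (0.68, 0.48 to 0.88) and PRSS30P (0.58, 0.39 to 0.78). Genes lower in LGL1-specific cells than in both others were CAVIN3 (-0.54, -0.86 to -0.22), LRP12 (-0.51, -0.73 to -0.29), PPARG (-0.50, -1.44 to 0.44), CCL20 (-0.48, -1.17 to 0.22) and TNF (-0.52, -0.90 to -0.13). NK receptor and innate-like genes as a list were 0.28 higher in unstimulated and 0.42 higher in stimulated LGL1-specific cells (median of 18 genes, percentile 100 of 10000 random lists in both states). In stimulated cells the medians were also 0.16 for cytotoxic genes (percentile 100), -0.32 for type 17 genes and -0.13 for early T cell receptor response genes (percentile 0 in both). The ACTB ratio of 3' to 5' probe sets differed between the same arrays, at -0.03 and 0.10 on the LGL1 and -0.36 and -0.18 on the bGL1-22 arrays.

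After adjustment, 0 genes differed between LGL1-specific and bGL1-22-specific cells (limma, smallest adjusted p = 0.158; 0 also with robust variances), with 889 at an unadjusted p under 0.05. The unadjusted 95% interval excluded 0 in 4.52% of all genes. The residual of the additive model also holds any differing aGalCer response, which widens the intervals. This share therefore cannot be read against the one that the level gives without any difference. The lack of calls does not show the populations to be alike. For 19524 genes (99.3%) the 95% interval lay within 1 log2 either way. The intervals cover the spread between these arrays. They leave out any spread between cultures or donors. In that respect they are too narrow for a difference between populations, as the p-values of the additive model are too small. The median absolute difference was 0.07, against 0.10 between LGL1 and aGalCer, and the 95th percentiles were 0.25 and 0.52. Of 22 panel genes, the unadjusted interval excluded 0 for 4: IL21 (-0.60, -0.87 to -0.32), TNF, IL2RA (-0.29, -0.56 to -0.03) and ZBTB16 (0.56, 0.22 to 0.90). For CXCL13 it ran from -3.02 to 2.59 around a difference of -0.21 and for IL17A from -1.84 to 0.36 around -0.74. These wide intervals reflect the differing aGalCer response (-4.70 and -1.80), which enters the residual of the additive model. CXCL13 lay at -5.01 and -4.76 on the unstimulated and at 0.08 and 0.25 on the stimulated LGL1 and bGL1-22 arrays. With 1 array each, larger differences are not excluded. The LGL1 and bGL1-22 arrays of the same state had exactly equal deposited values (tolerance 0) in 117 and 93 of 54675 probe sets, against 85 to 110 in the other pairs of arrays.

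**Figure D5:**
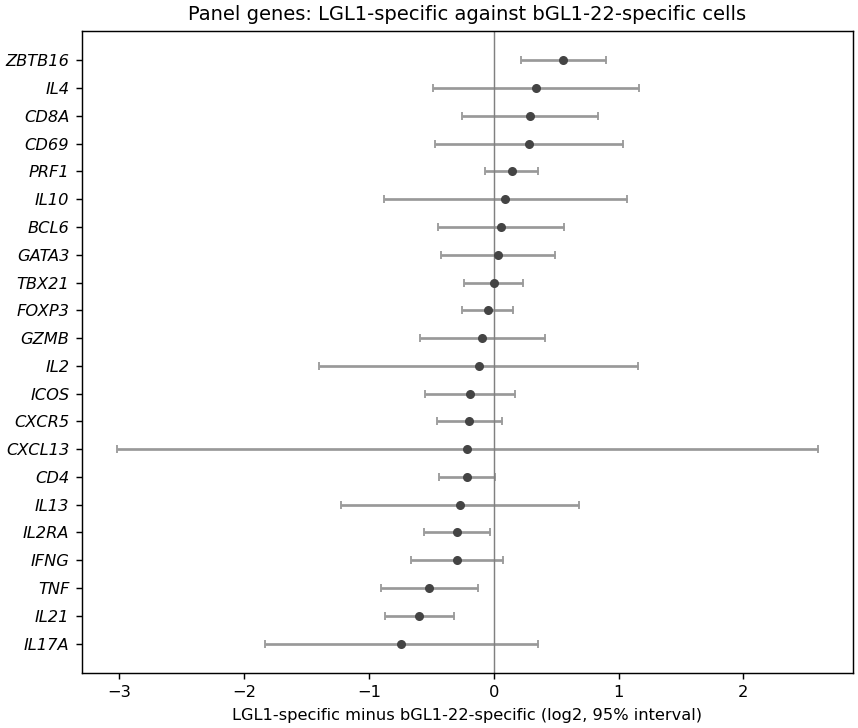
LGL1-specific minus bGL1-22-specific difference (x axis, log2) of the 22 measured panel genes, averaged over both states, with the unadjusted 95% interval of limma's additive model, which covers the spread between these arrays only. The intervals of IL21, TNF, IL2RA and ZBTB16 excluded 0, and that of CXCL13 was the widest.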

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

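The test of differing responses and the analyses restricted to 1 state were chosen after results were seen, as were the tests of low input for the first pattern and of genes already high in the unstimulated aGalCer array; the other tests were planned.

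Among the genes named for stimulation and the fixed panel, 9 had a response that differed between the aGalCer-specific population and the mean of the others, by a limma test of the difference itself that gave 231 genes in all. The difference was -4.70 for CXCL13, -2.69 for IL3, -2.07 for IL2, -1.80 for IL17A, -1.57 for IL13 and -1.19 for CD69 (adjusted p = 0.0368). It was 1.37 for ZBED2, 0.87 for TNFSF13B (adjusted p = 0.0425), which fell less in aGalCer-specific cells, and 0.85 for CD8A (adjusted p = 0.0452), which was lower there in both states. For CXCL13, CD69, ZBED2, TNFSF13B and CD8A, aGalCer-specific cells lay further from the others on the unstimulated arrays. For IL3, IL2, IL17A and IL13 they lay further from the others on the stimulated arrays. Each difference rests on 1 aGalCer pair of arrays against 2 pairs.

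The first pattern is the 122 genes that set aGalCer-specific cells apart in both states. Low RNA input on the unstimulated aGalCer array, whose poly-A controls were high, is argued against as the whole cause, since of the 315 genes apart on the unstimulated arrays alone, chosen without the stimulated arrays, 93.3% lay on the same side of both other populations on the stimulated arrays. For the 39 genes higher in aGalCer-specific cells, B cells or myeloid cells in that tetramer sort were sought through their list medians. These lay -0.088 and -0.016 log2 from the other populations, within the bound set beforehand for no such cells. A list median can stay flat while single members differ, as LYZ did in the other direction, so the test does not decide. For the 83 lower genes such cells in the LGL1 and bGL1-22 sorts stay open and were not tested, with MS4A1 at -1.03 to -0.20 and LYZ at -2.52 to -0.21 in aGalCer-specific cells. An effect of input on both arrays stays open, as the stimulated aGalCer array also had higher poly-A controls (0.08) than the other stimulated arrays (-0.45 and -0.40), and the specificity of the cells, and a different donor or culture, could also give this pattern and cannot be separated with 1 array per population and state.

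The second pattern is the 231 genes whose response differed in aGalCer-specific cells. A weaker stimulation of these cells as a whole is argued against as the whole cause, because 42.4% of the genes had a larger response there. Larger was taken in the direction of the mean response, which includes aGalCer-specific cells. The count can therefore take in genes of opposite sign, such as COL5A2 (-0.77, -0.43 and 1.84 in LGL1, bGL1-22 and aGalCer-specific cells). Low input on the unstimulated aGalCer array could account for part, and the test left it undecided: 32.5% of the genes had at least 50% of the difference in the stimulated arrays, between the bounds set beforehand. IL22 and PTGS2 differed in the stimulated arrays, which that array cannot produce, while CXCL13 and CD83 differed mainly in it (stimulated cells by 0.19 and 0.02, and by 0.39 and 0.32). A difference between the populations themselves stays open and was not tested apart from donor or culture.

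The third pattern is the high CXCL13, CD83 and CCL1 in unstimulated aGalCer-specific cells, CCL1 being 2.65 and 1.37 above the other populations. A candidate explanation is that part of the stimulation programme was already present there. Genes that rose by at least 1 log2 in LGL1 cells (708) were then expected to lie higher in unstimulated aGalCer than in unstimulated bGL1-22 cells, and their median was 0.114 higher; with the roles of the 2 populations exchanged it was 0.115 (742 genes). Genes that fell lay lower, with medians of -0.138 and -0.188, while among stimulated cells the rising genes lay at -0.033 and -0.011 and the falling genes at -0.065 and -0.099, so part of the shift of the falling genes was not particular to unstimulated cells. The signs follow the hypothesis, but every median fell short of the 0.2 set for it, so the test does not decide.

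For the stimulation test, 10 splits of the 6 arrays into 3 and 3 are possible, too few for a share under 0.05. The real split gave 6599 genes, 1 of the 10 splits reached that number, and the highest of the others gave 0. The other splits parted the arrays of only 1 population or exchanged the states of 1 population, so the stimulation effect entered their residual. Their 0 was thus set by the design, and no conclusion is drawn from it.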

How the results depend on the processing

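The largest-SD probe set, robust variances, the averaging of LGL1 and bGL1-22 as 1 unit, the single-state counts, the test of differing responses and the count with a 1 log2 minimum were chosen after the data were seen; quantile normalization, filters on dim probe sets and a variance trend were not run. Stimulation calls varied between 2271 and 3762 genes higher and between 2100 (without bGL1-22) and 3535 lower when each population was left out in turn, and 644 and 570 remained with a minimum of 1 log2. Without the population block 2792 and 2465 genes were called, 5185 of them shared with the 6599. Of 39 named genes in the stimulation test, between 36 and 39 kept their side of the threshold under each alternative. Sign changes, none past the threshold, were those of FOXP3 (-0.04 with the highest-mean probe set) and ZBTB16 (0.02 without bGL1-22 and 0.08 without aGalCer). Genes responding in all 3 populations numbered 809, and 277, 2102 and 1461 at 1.5 log2, at 1.5-fold and with the largest-SD probe set; leave-one-out counts ran from 878 to 1128. The aGalCer population was apart by 122 genes, and by 50 and 367 at those thresholds, 233 with the largest-SD probe set, 223 on stimulated and 315 on unstimulated arrays. For LGL1 these were 0, 5, and 7 unstimulated; for bGL1-22 they were 0, 15, 8, 7 and 14. The aGalCer against LGL1 contrast gave 855 genes with the largest-SD probe set, against 540. The response difference gave 126 after centring and 502 with the largest-SD probe set, against 231. Camera with an estimated correlation called 0 of 25 lists, and without the population block 3 of the 15 calls ended. The largest-SD rule picks variable probe sets by construction. The highest-mean rule, on centred values, picks those with the most positive deviations. For other moves the cause was not tested. Of 3964 called genes with several probe sets, all probe sets agreed in direction in 3098 (78.2%). Centred values hold no signal over background, so how far it limits dim genes is unknown.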

Other observations

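The tests reported here were planned, while MKI67, CCNE2, PSAP and GALC were named after their values were seen. Cell cycle genes moved in opposite directions with stimulation: 10 of 29 rose and 11 fell (12 and 14 adjusted over the list alone; camera adjusted p = 0.859, fry 0.0586), and the median (-0.09) and mean (0.12) differed in sign. CDC6 and MCM2, which license replication origins, rose by 2.20 ± 0.02 and 1.63 ± 0.10 (SD, n = 3), while TOP2A and CENPF, which act in chromosome segregation, changed by -0.99 ± 0.26 and -0.88 ± 0.18. MKI67, the proliferation marker, changed by -0.87 ± 0.03 and CCNE2, a cyclin of S phase entry, by 0.87 ± 0.11. Apoptosis and survival genes rose in 8 and fell in 5 of 17 (9 and 5 adjusted over the list alone; adjusted p = 0.409, fry 0.342), with PMAIP1 at 1.98 ± 0.58, BCL2A1 at 1.75 ± 0.83, CASP8 at -0.73 ± 0.10 and BMF at -1.66 ± 0.54.

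Genes of glycosphingolipid metabolism, the class to which the sorting lipids belong, also went both ways: 6 of 22 rose and 11 fell (6 and 11 adjusted over the list alone; camera adjusted p = 0.113, fry 0.00212). UGCG, which makes glucosylceramide, rose by 1.02 ± 0.24, and B4GALT5, which acts on it to make lactosylceramide, by 0.90 ± 0.30. NPC2, a lysosomal cholesterol carrier, changed by -1.79 ± 0.09, and ST3GAL5, which makes the ganglioside GM3, by -1.24 ± 0.03. PSAP, the precursor of the saposins that assist lysosomal lipid breakdown, changed by -0.63 ± 0.13, and GALC, a lysosomal galactosylceramidase, by -0.94 ± 0.41. All 6 of these genes had the same sign in 3 of 3 populations.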
